A study of Danio rerio with 8 samples.

How the data were processed

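Total RNA of pooled whole larvae from 4 clutches was sequenced, with 1 mutant and 1 sibling control library per clutch, as the labels state. Reads were made on a BGI DNBSEQ instrument and filtered with SOAPnuke 1.5.2. The submitters' notes name GRCz11, HISAT2 2.0.4, Bowtie2, RSEM and limma without stating the role or order of each. The per-library table was deposited by the authors as normalized values, and its log2 CPM unit was read from the numbers themselves, because 2 to the power of the values sums to nearly the same total in every library and because values below 0 occur (lowest -5.02, highest 14.04). The quantiles of the 8 libraries were nearly identical, so the authors are taken to have quantile-normalized them. Equal quantiles also make the totals equal, so the totals do not settle the unit, which remains an inference. The second table deposited by the authors holds their comparison of mutants with controls, with log2 fold change and mean log2 CPM, a p-value and an adjusted p-value per gene, and a moderated statistic and a log odds score of the kind that limma reports. The score values of the authors' deposited table were not used here. No counts are in these tables, so the depth per library and the precision it gives are unknown.

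The table held 20409 genes. A gene was tested if at least 4 of the 8 libraries reached 0 log2 CPM, which kept 20154. The 8 libraries were compared with limma 3.58.1 in R 4.3.3, with a linear model of genotype, and with empirical Bayes moderation with a mean-variance trend and robust estimation. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The values were already logged, so no pseudocount was added and no model for counts was used. ccdc103 was also tested with an exact two-sided permutation test over the 70 arrangements of the libraries.

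Clutch numbers pair the libraries, since the labels state that each number is a clutch. This was checked on the values before the fits were compared. Deviations from the group means correlated across genes by 0.72, 0.50, 0.50 and 0.30 between the libraries of clutches 1 to 4, and in 4 of 4 clutches each library correlated best with its clutch mate. The fit without clutch was fixed as the main one, and the fit with clutch as a block is given beside it where it changed a call or moved a count by more than 1.5 times.

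The 39 gene lists, 1842 symbols of which 1581 were measured, and the rule for naming genes were fixed before the data were examined. Lists were tested with camera of limma at its preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the lists. With an estimated correlation, camera also takes its degrees of freedom from the few libraries rather than from the many genes. A call lost in that test is therefore not by itself a sign of correlation among the members of a list. Named genes were ccdc103, then, of called genes with the same direction in 4 of 4 clutches, a mean of at least 5 CPM in the higher group and a symbol that is not a clone or predicted name, the 10 largest rises, the 10 largest falls and the 5 smallest adjusted p. Up to 4 called members of each list were added, or up to 2 of the most abundant members where none was called. Genes past the threshold numbered 15, so the provision for fewer than 10 was not used. The rule was also applied to the blocked fit, a step added after the data were seen. Other motile cilia genes, the Reissner fibre genes that did not pass, npas4b, gfap, ptx3b, further cyp genes and clone-named genes were named after their values were seen.

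Chromosomes and gene order came from RefSeq genes of GRCz12tu, matched by gene ID (19636 genes of the table), and 19422 tested genes had a chromosome. The files use GRCz11, so no positions are given, and the planned window of 5 Mb around ccdc103 was replaced by the 100 tested genes on each side of it. Calls inside and outside a region were compared with Fisher's exact test, two-sided.

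The procedure was tested on simulated data of the same 20154 genes, in which 200 genes were changed. Without the block it recovered 0% of genes changed by 0.5 log2 units and 41% of those changed by 1, with 0 unchanged genes called. With the block it recovered 29% and 70%, with 1 unchanged gene called. The changed list was called in both fits and 0 of 38 unchanged lists were. The simulated lists held random genes with independent noise, so this does not show how the test treats lists of correlated genes. Alternatives were a clutch block, no filter, a filter on a mean of 5 CPM, median-ratio rescaling in place of other size factors, quantile normalization again, no trend and no robust estimation, array weights, exclusion of the chromosome of ccdc103, and exclusion of each library and each clutch.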

Results

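Gene expression was measured by RNA sequencing of whole zebrafish larvae at 4 days post fertilization. Each of the 8 libraries was made from 30 pooled larvae. The larvae carried the smh (schmalhans) mutation of ccdc103, a gene needed to attach dynein arms to the axoneme of motile cilia, so that the cilia of homozygous mutants are paralysed. Mutant larvae were picked by their downward curled tail, and the sibling controls were a mixture of wild-type and heterozygous larvae. From each of 4 clutches there was 1 mutant library and 1 control library, which gave 4 mutants and 4 controls. The series asked how paralysis of cilia changes gene expression. The values used here are taken to be log2 CPM (read counts scaled to a common library total) for 20409 genes. The authors had already made them equal in distribution between libraries, so they sum to between 997999 and 998006 CPM in every library. The sequencing depth of the libraries is unknown.

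Expression of ccdc103 itself (NCBI gene ID 437026) was low in both genotypes. The sibling controls of clutches 1 to 4 had 0.64, 1.00, 0.67 and 0.40 log2 CPM, and the mutants had 0.55, 0.33, 0.33 and 1.00 log2 CPM. The means were 0.68 ± 0.25 in controls and 0.55 ± 0.31 in mutants (SD, n = 4). The difference of -0.13 log2 units (SE 0.23) had a 95% confidence interval of -0.62 to 0.37 in limma and was within the spread between libraries (exact two-sided permutation p = 0.486, with 0.0286 the smallest p that 4 against 4 libraries allow). Transcript level therefore did not separate the genotypes, and it checks the labels only if the mutant transcript is degraded.

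In the comparison of mutants with siblings, foxj1a (gene ID 767737), the transcription factor that switches on motile cilia genes, rose 2.57-fold, from 2.31 ± 0.12 to 3.67 ± 0.11 log2 CPM (SD, n = 4). The kidney tubule transcription factor hnf1bb (gene ID 324283) rose 2.28-fold, from 2.93 ± 0.09 to 4.12 ± 0.11 log2 CPM. glis3 (gene ID 571000), a zinc finger transcription factor, rose 3.62-fold, from 2.22 ± 0.31 to 4.07 ± 0.42 log2 CPM, the largest rise among genes called without a clutch term. Each of these was higher in mutants in 4 of 4 clutches.

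In numbers, 15 of 20154 tested genes differed between mutants and siblings at an adjusted p under 0.05 (limma, Benjamini-Hochberg), with 11 higher and 4 lower in mutants. Of these, 13 differed at least 2-fold, with 10 higher and 3 lower. The adjusted p was 0.00144 for foxj1a, 0.00146 for hnf1bb and 0.0074 for glis3. The smallest unadjusted limma p, 1.08e-07, was that of the clone-named gene si:dkey-39a18.1 (adjusted p = 0.00144). It rose 3.18-fold, from a mean of 0.75 to 2.42 log2 CPM, in 4 of 4 clutches. Other named genes also changed in 4 of 4 clutches each. The sodium-coupled sugar transporter gene slc5a9 rose 2.29-fold (SE 0.13 log2 units, limma adjusted p = 0.00403), and mfsd4ab, of the major facilitator superfamily, rose by 1.39 ± 0.18 (SE, limma adjusted p = 0.0148). For slc4a2a, an anion exchanger gene, the rise was 0.80 ± 0.10 log2 units (SE, limma adjusted p = 0.00979). pdzk1ip1 rose by 1.04 ± 0.16 log2 units (SE, limma adjusted p = 0.043). The pentraxin gene ptx3b rose by 1.42 ± 0.20 log2 units (SE, limma adjusted p = 0.0231). The bile acid synthesis gene hsd3b7 fell by 0.76 ± 0.10 log2 units (SE, limma adjusted p = 0.0202) in 4 of 4 clutches.

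Several of these calls were lost when 1 library was left out, which also lowers power and leaves the clutches unbalanced. Without the block, those of foxj1a, hnf1bb and slc5a9 held whichever library was left out. The call of glis3 was lost without the mutant of clutch 3 or 4 (limma adjusted p = 0.051 and 0.057), and that of mfsd4ab without the control of clutch 2 or 4 or the mutant of clutch 3 or 4 (adjusted p up to 0.104). slc4a2a and the tektin gene tekt4 lost the call without the control of clutch 2 or the mutant of clutch 2, 3 or 4 (adjusted p up to 0.0771 for each). hsd3b7 lost it without the control of clutch 2, 3 or 4 or the mutant of clutch 1, 2 or 4 (adjusted p up to 0.123), and pdzk1ip1 without either library of clutch 2, 3 or 4 (adjusted p up to 0.202). pdzk1ip1 also lost the call with the filter on a mean of 5 CPM, with median-ratio rescaling, in limma without trend and robust, and without genes on the ccdc103 chromosome. ptx3b and si:dkey-39a18.1 were not followed through these alternatives. With clutch as a block, the 9 genes followed kept their calls in every alternative that tested them.

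Libraries of the same clutch deviated together, and with clutch as a block the same test called 472 genes, 191 higher and 281 lower in mutants. All 15 genes above were among them, and 39 of the 472 differed at least 2-fold, 26 higher and 13 lower. The blocked count depends on how gene variances were moderated, since the blocked fit without a mean-variance trend and without robust moderation called 50 genes. In that fit 72 named genes lost the blocked call, and 37 lost it without clutch 2 and 37 without clutch 4. Among the added calls, slc34a1a, a phosphate transporter gene of the kidney proximal tubule, rose 2.07-fold (blocked limma adjusted p = 0.00418), ponzr4 rose 1.88-fold (adjusted p = 0.000332), cox4i1l rose 1.88-fold (adjusted p = 0.00174) and clec19a, among the 100 tested genes on one side of ccdc103, rose 1.96-fold (adjusted p = 0.000582). On the lower side, the metallothionein gene mt2 went from 6.26 ± 0.46 to 5.36 ± 0.36 log2 CPM (SD, n = 4) and was 1.86-fold lower within clutches (blocked limma adjusted p = 7.72e-07, 0.611 without the block). The phospholipase gene pla2g1b was 1.95-fold lower, the transglutaminase gene tgm2a 1.92-fold, the small heat shock gene hspb9, the 5th tested gene from ccdc103, 1.90-fold, the matrilin gene matn3b 1.85-fold and tm6sf2 1.84-fold. The retinal opsin-like gene rgra was 1.72-fold lower, the sulfotransferase gene sult1st2 1.76-fold and the meprin gene mep1a.1 1.72-fold. Each of these falls held in 4 of 4 clutches and passed the blocked test but not the test without the block. Leaving out single libraries gave 7 to 21 calls without the block, with 7 without the mutant of clutch 4, 8 without the mutant of clutch 3, and 9 without the control or without the mutant of clutch 2. Leaving out a whole clutch gave 25 calls without clutch 1, 1 each without clutch 2 and without clutch 3, and 0 without clutch 4, while the blocked fit gave 419, 235, 447 and 178.

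**Figure D1:**
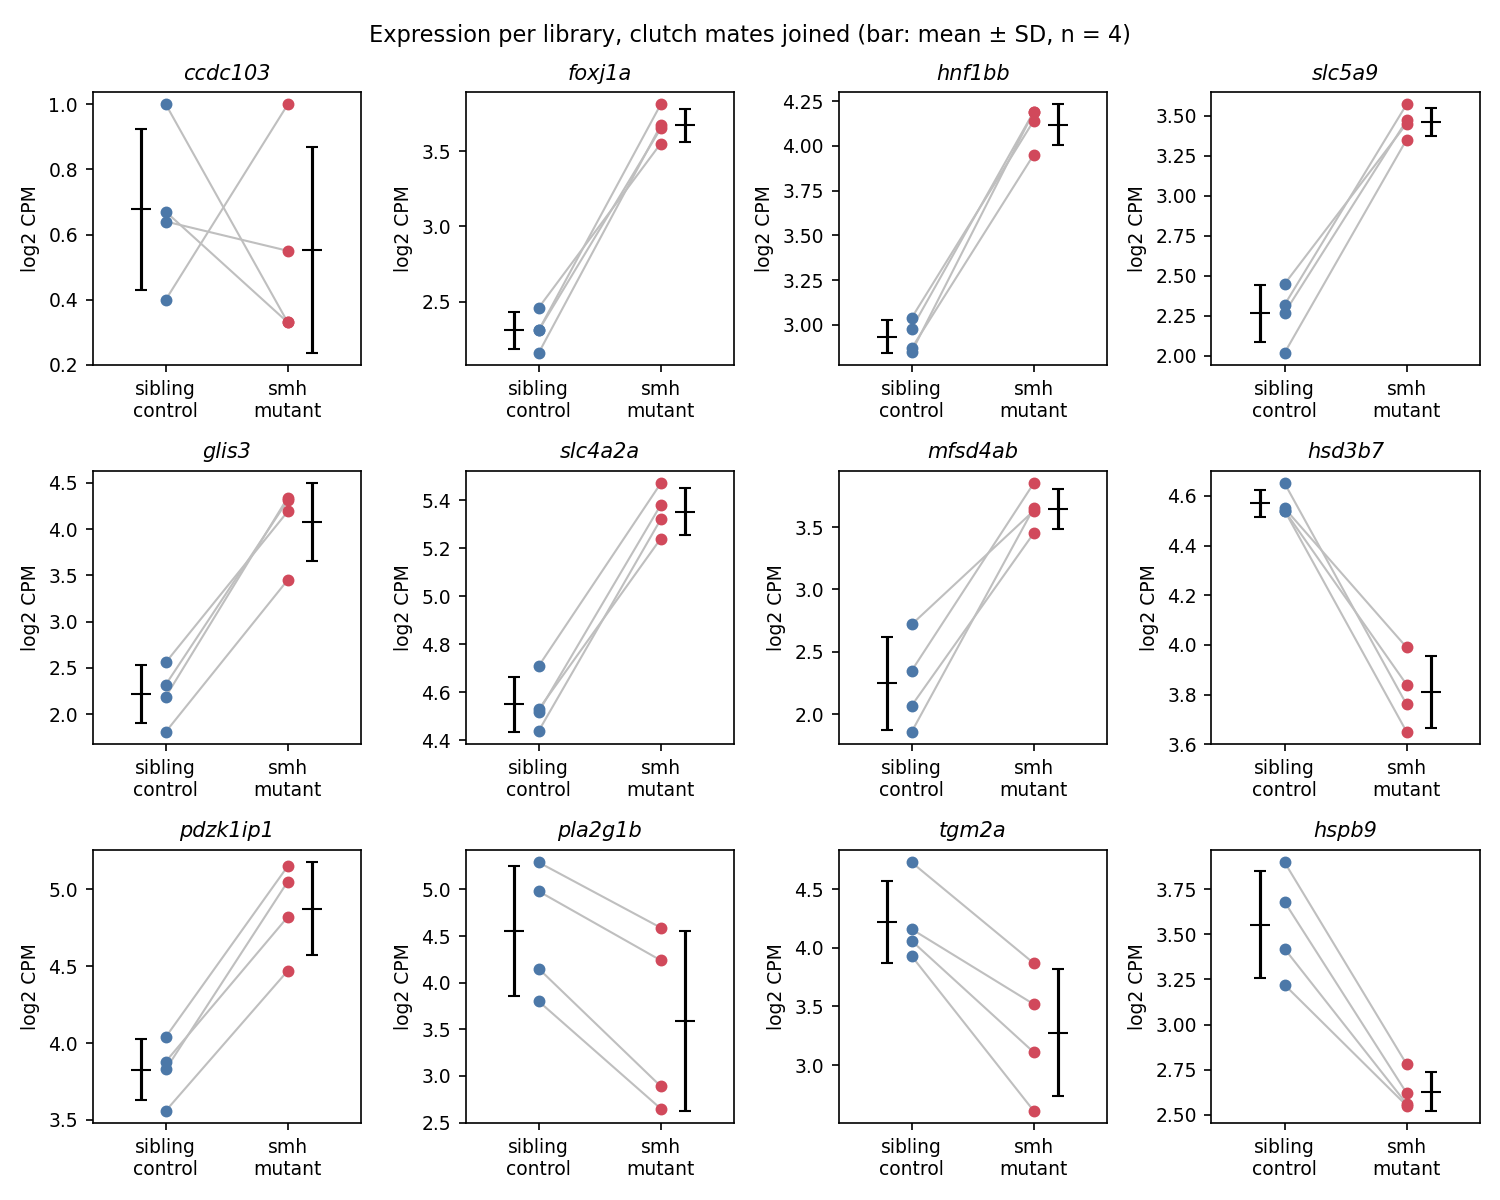
Expression of 12 genes in log2 CPM (y axis) in the 4 sibling control libraries (blue) and the 4 smh mutant libraries (red), with libraries of the same clutch joined by a grey line and the mean ± SD beside each group. The y axes differ between panels and do not start at 0. The lines of foxj1a, hnf1bb and glis3 rise in 4 of 4 clutches, those of pla2g1b and hspb9 fall in 4 of 4, and those of ccdc103 cross.

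Genes of motile cilia were higher in mutants as a group. Of 103 measured members of the list of axoneme and assembly genes, 36 rose and 1 fell with clutch as a block, and 2 rose, foxj1a and tekt4, without it. Adjusted over the list alone, 54 rose and 2 fell without the block, and 63 rose and 4 fell with it. The median log2 fold change of the list was 0.52, and 92 of the 103 members lay above 0. The tektin gene tekt4 rose 2.36-fold (limma adjusted p = 0.0125). Within clutches, the dynein heavy chain genes dnah5l, dnah5, dnah7 and dnah2 rose by 0.68, 0.59, 0.76 and 0.52 log2 units. The radial spoke genes rsph10b, rsph9 and rsph4a rose by 1.14, 1.38 and 0.68 log2 units, and hydin, of the central pair, rose by 0.60 log2 units. foxj1b, a paralog of foxj1a, rose by 0.51 log2 units (blocked limma adjusted p = 0.0127). The member that fell, cfap70, lies on the chromosome of ccdc103 and was lower by 0.59 log2 units (SE 0.11 in the blocked fit, adjusted p = 0.00521).

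The list passed camera without the block (adjusted p = 6.7e-51) and with it (7.52e-30), also with an estimated correlation (adjusted p = 0.000924 without the block and 0.0224 with it). Its median was above 0 in each clutch, at 0.38, 0.49, 0.50 and 0.52 in clutches 1 to 4. Many members were expressed at a low level, and for the 24 with a mean of at least 5 CPM the median was 0.27. Genes of intraflagellar transport and ciliary trafficking, which build motile and immotile cilia alike, had a median of 0.06 over 58 members, and no member passed in either fit or adjusted over the list alone (limma, 2 members at an unadjusted p under 0.05 without the block and 8 with it). This list passed camera (adjusted p = 0.0227) but not with an estimated correlation (adjusted p = 0.31 with an estimated correlation). Its most abundant members kif3a and pkd1a differed by 0.02 and 0.12 log2 units.

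In the list of the Reissner fibre, urotensin peptides and neurons in contact with the cerebrospinal fluid, the peptide gene urp2 was lower in mutants. It was 2.22-fold lower, at 0.90 ± 0.06 log2 CPM in controls and -0.25 ± 0.30 in mutants (SD, n = 4), and passed with clutch as a block (limma adjusted p = 0.0149) but not without it (adjusted p = 0.157). It was also the 1 member to fall adjusted over the list alone, in both fits. Values of urp1 (log2 fold change -0.49), scospondin (-0.31) and pkd2l1 (-0.24) did not pass, and the list of 21 members had a median of -0.04 (camera adjusted p = 0.0645).

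Kidney genes moved in both directions. In the list of pronephros and podocyte genes, 6 of 42 measured members rose and 2 fell with clutch as a block, and 14 rose and 8 fell adjusted over the list alone. Without the block, hnf1bb and slc4a2a rose, by either adjustment. The podocyte transcription factor wt1a rose 1.46-fold within clutches (blocked limma adjusted p = 0.00724). The list median was 0.10 (camera adjusted p = 0.0187), and the call was lost with an estimated correlation (adjusted p = 0.464 with an estimated correlation).

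Genes of digestion were lower in mutants within clutches, but neither of the 2 lists passed camera with an estimated correlation in either fit. In the exocrine pancreas list, 20 of 26 measured members fell with clutch as a block and 0 passed without it (limma, 4 at an unadjusted p under 0.05), and 25 fell adjusted over the list alone in the blocked fit (0 without the block). All 26 members had a log2 fold change below 0, with a median of -0.52. The carboxypeptidase genes cpa1 and cpa5 were 1.71-fold and 1.42-fold lower, and the elastase gene ela3l was 1.59-fold lower (blocked limma adjusted p = 4.48e-05, 0.000164 and 0.000314). In the intestine list, 15 of 39 members fell with the block and 0 without it (limma, 5 at an unadjusted p under 0.05), with 25 falling and 1 rising adjusted over the list alone in the blocked fit (0 without). The glucose transporter gene slc5a1 was 1.58-fold lower, the aminopeptidase gene anpepb 1.46-fold, the amino acid transporter gene slc6a19b 1.63-fold and the fatty acid binding protein gene fabp2 1.31-fold, each in 4 of 4 clutches. The intestine median was -0.37.

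Both digestive lists passed camera without the block (adjusted p = 3.06e-16 for exocrine pancreas and 7.32e-08 for intestine) and lost the call with an estimated correlation (adjusted p = 0.367 with an estimated correlation for each). The medians of the 4 clutches were -0.74, -0.35, -0.32 and -0.73 for exocrine pancreas and -0.38, -0.23, -0.16 and -0.58 for intestine, and clutches also differed from each other in these genes, with an SD of 0.80 log2 CPM between the control libraries for cpa1. Other divisions of the 8 libraries gave absolute medians of up to 0.84 for exocrine pancreas and 0.66 for intestine. Among the 8 divisions that part clutch mates, the largest others were 0.37 and 0.23, but 8 are too few for a share under 0.05. Without the mutant of clutch 1 the unblocked medians were -0.29 for exocrine pancreas and -0.18 for intestine; the intestine median was -0.22 without the mutant of clutch 4, -0.19 without the control of clutch 3 and -0.23 without the control of clutch 2. The liver list did not move as a group (40 members, median 0.03, mean -0.07, camera direction down, adjusted p = 0.924). In it, 4 members fell and 1 rose with the block, 8 fell and 6 rose adjusted over the list alone, and 0 passed without the block (limma, 0 at an unadjusted p under 0.05). cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.45-fold lower (blocked limma adjusted p = 0.000532), cyp3a65 was 1.54-fold and tdo2b 1.85-fold lower, and cp, ceruloplasmin, was 1.24-fold higher (adjusted p = 0.0175). Endocrine pancreas genes had a median of -0.06 over 15 members (camera adjusted p = 0.111), with no member passing in either fit or adjusted over the list alone (limma, 0 at an unadjusted p under 0.05 in both), and the abundant members neurod1 and isl1 each differed by -0.04.

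Blood protein, heart and blood cell lists had medians slightly above 0, but none passed camera with an estimated correlation in either fit. Of 38 complement and acute phase genes, 7 rose with the block and 0 passed without it (13 rose and 1 fell adjusted over the list alone in the blocked fit, and 1 rose without the block), with a median of 0.10. The complement genes c4b, c6, c7a and c3a.1 were 1.71-fold, 1.54-fold, 1.40-fold and 1.27-fold higher. The heart list had a median of 0.14 over 29 members. In it the natriuretic peptide gene nppa was 1.74-fold higher and the myosin gene myh7l 1.26-fold higher with the block, 7 rose and 1 fell adjusted over the list alone, and 0 passed without the block. Among 26 erythroid genes, with a median of 0.16, 5 rose with the block (9 adjusted over the list alone, 0 without the block). The globin genes hbbe1.1, hbae1.2 and hbae3 and the anion exchanger gene slc4a1a were 1.34-fold, 1.51-fold, 1.23-fold and 1.28-fold higher. These 4 lie on the chromosome of ccdc103, and globin genes have near-identical copies, so how reads were divided among them is uncertain. Connective tissue genes had a median of 0.08 over 75 members, and 5 rose and 2 fell with the block (12 and 2 adjusted over the list alone, 0 without the block), among them the fibronectin genes fn1b and fn1a (1.28-fold and 1.27-fold higher), the elastin gene elnb (1.31-fold higher) and the collagen gene col9a1b (1.37-fold lower). All 4 lists passed camera, with adjusted p of 0.000147 for complement, 0.0017 for heart, 0.000147 for erythroid and 0.00114 for connective tissue. None of these calls held with an estimated correlation (adjusted p = 0.386, 0.31, 0.384 and 0.31 with an estimated correlation, in that order).

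Brain cell lists showed little change in whole larvae. Over 43 radial astroglia genes the median was -0.01, and no member passed in either fit or adjusted over the list alone (limma, 0 at an unadjusted p under 0.05 without the block and 6 with it; camera adjusted p = 0.761). The abundant astroglial genes apoeb and slc1a2b differed by -0.08 and 0.07 log2 units, and gfap by -0.15. Pan-neuronal and synaptic genes had a median of -0.02 over 65 members (camera adjusted p = 0.283), with 1 member, the synuclein gene sncga, 1.21-fold lower with the block, also the 1 passing adjusted over the list alone. The median over 27 neurotransmitter phenotype genes was 0.00 (camera adjusted p = 0.963), and the serotonin transporter gene slc6a4a was 0.27 log2 units higher with the block (adjusted over the list alone 1 rose and 1 fell). Receptors of glutamate, GABA and glycine had a median of -0.01 over 53 members and no call in either fit or adjusted over the list alone (0 at an unadjusted p under 0.05 without the block and 4 with it, camera adjusted p = 0.924), with grin1b and grin1a at 0.09 and 0.02. The clutch medians of this list were 0.05, 0.00, -0.08 and -0.07. Without the block it passed camera as lower without the control of clutch 1 (median -0.14) and as higher without its mutant (median 0.11), and with the block the median was -0.04 without either of these libraries and the list did not pass (camera adjusted p = 0.388 and 0.395). Oligodendrocyte and Schwann cell genes had a median of -0.04 over 27 members and no call in either fit or adjusted over the list alone (0 at an unadjusted p under 0.05 without the block and 3 with it, camera adjusted p = 0.339), with pmp22b at -0.02 and cldn19 at 0.00.

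Neuropeptide and pituitary genes were lower in mutants. Their median was -0.15 over 38 members, of which 33 lay below 0. With the block 3 fell, the growth hormone gene gh1 (1.35-fold), tac3a (1.64-fold) and the granin gene scg2b (1.18-fold), and gh1 lies on the chromosome of ccdc103. Adjusted over the list alone, 4 fell and 1 rose with the block, and 0 passed without it. The list passed camera without the block (adjusted p = 3.03e-07), also with an estimated correlation (adjusted p = 0.013). In the blocked fit it passed camera (adjusted p = 2.06e-06) but not with an estimated correlation (adjusted p = 0.185 with an estimated correlation). The correlation estimated there was -0.02, below the preset 0.01, so this loss did not come from correlation among members. Immediate early genes, which respond to neuronal activity and other stimuli, had a median of -0.10 over 44 members (camera adjusted p = 0.00107, adjusted p = 0.511 with an estimated correlation). In this list mych was 1.32-fold lower with the block (2 fell adjusted over the list alone, 0 without the block), and npas4b, at a log2 fold change of -0.72, did not pass (blocked limma adjusted p = 0.0547).

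Photoreceptor genes had a median of -0.15 over 68 members, and 8 fell with the block (25 fell and 1 rose adjusted over the list alone, 0 without the block). They included the rod transducin gene gngt1 (1.35-fold lower), the cone genes arr3b (1.28-fold lower) and pde6ha (1.48-fold lower), and rbp4l (1.37-fold lower). The list passed camera (adjusted p = 1.01e-09) and lost the call with an estimated correlation (adjusted p = 0.367 with an estimated correlation). Lens genes had a median of 0.11 over 49 members (camera adjusted p = 0.492), a value set by clutch 2, where it was 0.54, against -0.19, -0.02 and 0.05 in clutches 1, 3 and 4. The lens list passed camera as lower without the control of clutch 2 (median -0.07) and as higher without the control of clutch 1 (median 0.21), and likewise with the block (medians -0.04 and 0.19). The lens gene grifin, on the chromosome of ccdc103, was 1.39-fold lower with the block and was the 1 lens gene to pass, also adjusted over the list alone. Among 42 genes of the inner ear and hair cells (median 0.01, camera adjusted p = 0.924), pvalb9 was 1.27-fold and the otolith gene oc90 1.71-fold higher with the block (2 also adjusted over the list alone, 0 without the block).

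Stress and metabolic lists were lower or flat. The glucocorticoid and stress list had a median of -0.13 over 33 members, and tat, pck1 and rasd1 were 1.41-fold, 1.19-fold and 1.36-fold lower with the block (6 fell adjusted over the list alone, and 1 without the block). Cholesterol synthesis genes had a median of -0.10 over 30 members, with msmo1 and nsdhl 1.31-fold and 1.32-fold lower (4 fell adjusted over the list alone, 0 without the block). In the p53 and apoptosis list, with a median of -0.10 over 28 members, gadd45ab and cdkn1a were 1.42-fold and 1.25-fold lower (2 fell adjusted over the list alone, 0 without the block). These 3 lists passed camera, with adjusted p of 0.00127, 0.00585 and 0.00585, and lost the call with an estimated correlation (adjusted p = 0.31, 0.519 and 0.384 with an estimated correlation). Circadian clock genes passed in the blocked fit (median -0.08 over 42 members, camera adjusted p = 0.000405, adjusted p = 0.223 with an estimated correlation) but not without the block (adjusted p = 0.241), and nfil3-6, on the chromosome of ccdc103, was 1.53-fold lower (4 fell adjusted over the list alone). The same held for the cell cycle (median 0.04 over 60 members, adjusted p = 0.00855 with the block, 0.51 with an estimated correlation, and 0.0636 without the block), where cenpf was 1.21-fold higher and was the 1 member to pass, also adjusted over the list alone. It held as well for the notochord (median -0.04 over 37 members, adjusted p = 0.0212 with the block, 0.223 with an estimated correlation, and 0.0575 without the block), where matn3b, vgll2b, col9a1b and ntd5 fell (6 adjusted over the list alone). Hypoxia genes had a median of 0.00 over 45 members (camera adjusted p = 0.945), with ndrg1a and pdk1 1.23-fold and 1.21-fold higher and ndrg1b 1.29-fold lower (2 rose and 2 fell adjusted over the list alone). Unfolded protein and heat shock genes also had a median of 0.00 over 51 members (camera adjusted p = 0.492), with hspb9 and hspb11 1.90-fold and 1.54-fold lower (3 fell adjusted over the list alone, 2 without the block).

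Muscle, immune and surface lists had medians near 0 and did not pass camera in either fit. The medians and camera adjusted p without the block were -0.04 and 0.0636 for 52 fast muscle genes, 0.00 and 0.783 for 16 slow muscle genes, and -0.07 and 0.131 for 35 genes of muscle atrophy and regeneration. In these, acta1b, tnni2a.4, mybpc2a, myoz2a and ankrd1b changed by -0.38, -0.26, -0.40, -0.45 and -0.27 log2 units and ryr3 by 0.29 with the block, and mybpc2a is among the 100 tested genes on one side of ccdc103. Adjusted over the list alone the counts were the same with the block, and 1 fast and 1 slow muscle gene fell without it. The medians were -0.08 for 29 microglia and macrophage genes (adjusted p = 0.255), -0.03 for 15 neutrophil genes (adjusted p = 0.396) and 0.02 for 36 inflammatory and interferon genes (mean -0.04, camera direction down, adjusted p = 0.492). With the block, grn1 was 1.45-fold lower and cxcl12a was 1.18-fold higher, and the 1 neutrophil call, cpa5, is also a member of the exocrine pancreas list. Adjusted over the list alone, 1 fell in each of the first 2 lists, and 1 rose and 1 fell in the inflammatory list. Epidermis and ionocyte genes had a median of -0.03 over 51 members (adjusted p = 0.131), with the keratin genes krt92, krt15 and krt97 1.21-fold, 1.19-fold and 1.18-fold lower (5 fell and 2 rose adjusted over the list alone). Vascular endothelium (37 members, median 0.03, adjusted p = 0.177, apln and aqp1a.1 at 0.02 and 0.06) and left-right, nodal or planar pathway genes (16 members, median 0.07, adjusted p = 0.0794, ptch1 and hhip at 0.04 and 0.09) had no call in either fit or adjusted over the list alone (limma, 0 and 1 at an unadjusted p under 0.05 without the block and 4 in each with it).

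**Figure D2:**
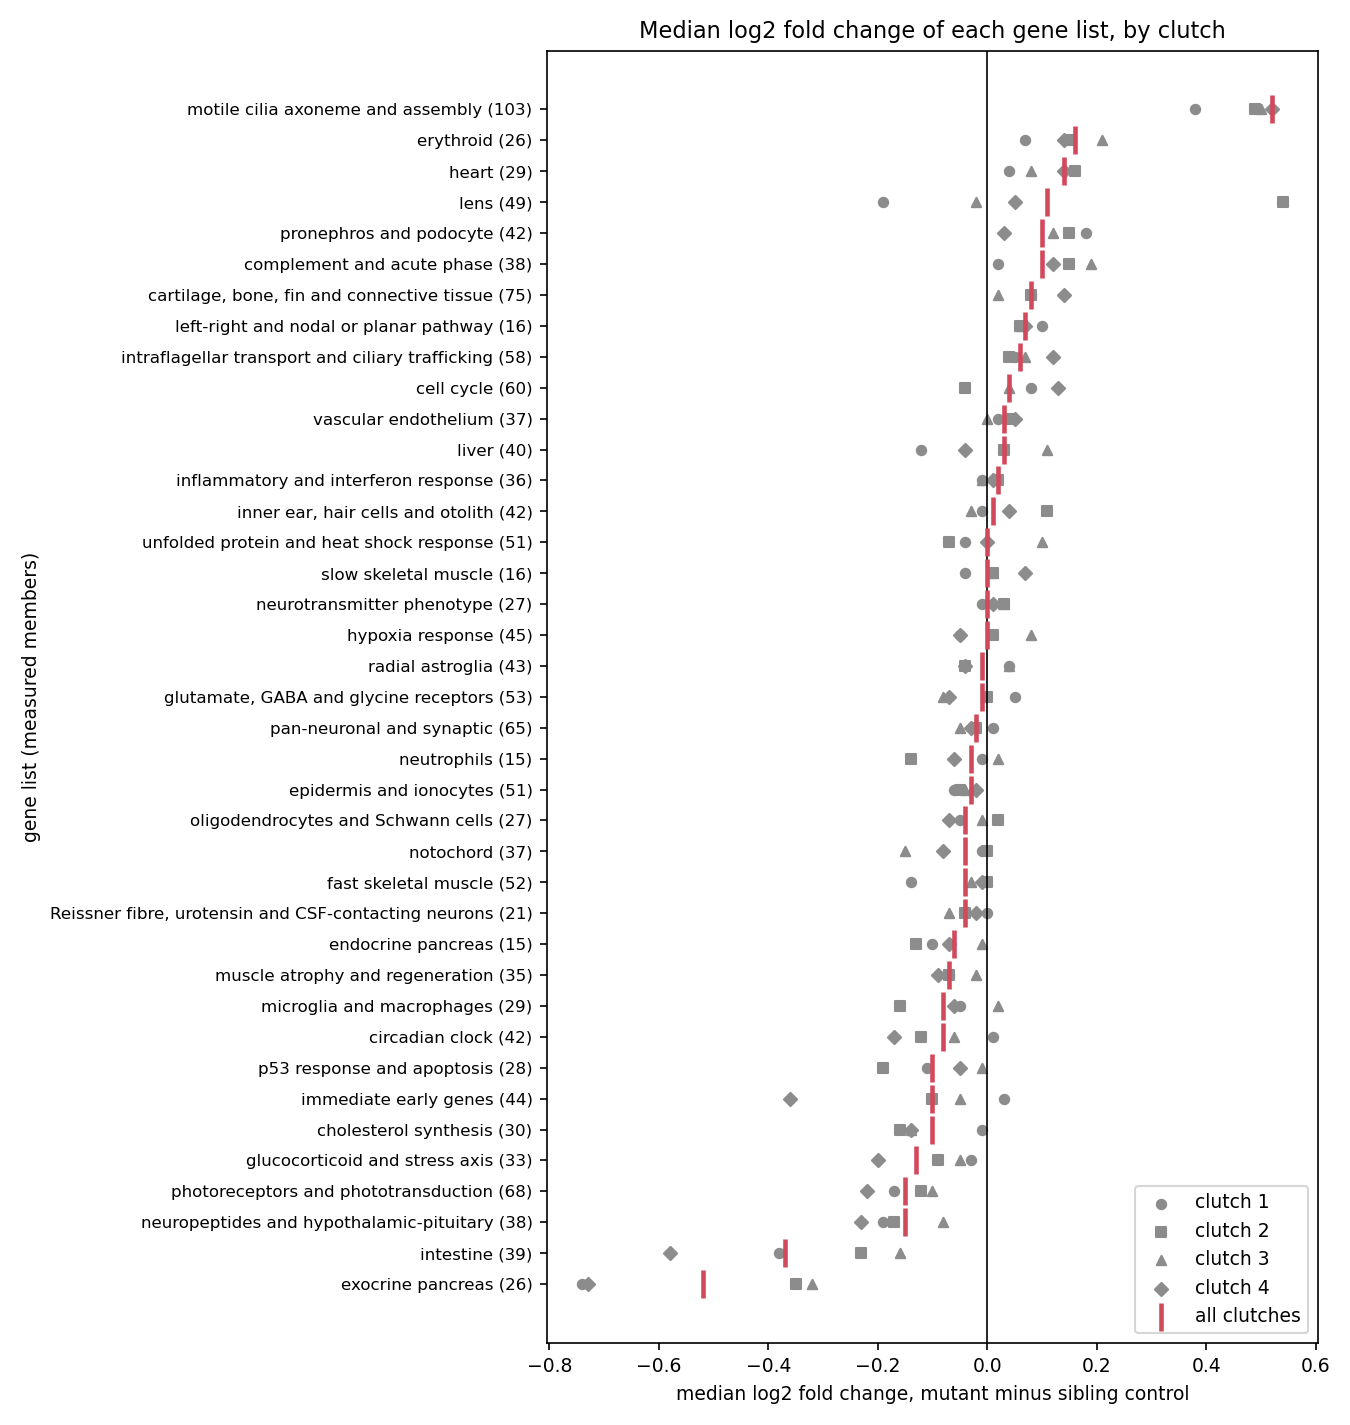
Median log2 fold change, mutant minus sibling control (x axis), of each of the 39 gene lists (y axis, with the number of measured members), in each of the 4 clutches (grey symbols) and over all clutches (red bar). The motile cilia list lies highest, with clutch medians from 0.38 to 0.52, and the exocrine pancreas list lowest, with clutch medians from -0.74 to -0.32.

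Of the 39 lists, 15 passed camera without the block, 7 higher and 8 lower, and 18 passed with it, 8 higher and 10 lower. With an estimated correlation 2 lists passed without the block, motile cilia and neuropeptides, and 1 with it, motile cilia. The other 17 lists called with the block had adjusted p of 0.185 to 0.51 with an estimated correlation. fry, which tests whether the genes of a list move on balance one way, called motile cilia and neuropeptides in both fits and photoreceptors with the block (adjusted p = 0.0306). Other divisions of the 8 libraries gave up to 20 lists by camera without the block where 3 of 4 libraries stayed with their genotype (16 divisions), and up to 17 where each side held 2 of each genotype (18 divisions).

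Genes on chromosome 3, which carries ccdc103, were called more often than others. Without the block, 6 of 1010 tested genes on this chromosome were called against 9 of 18412 on the others (odds ratio 12.2, 95% confidence interval 3.57 to 38.5, two-sided Fisher's exact p = 6.5e-05). With the block it was 58 against 400 (odds ratio 2.74, interval 2.03 to 3.65, Fisher's exact p = 3.35e-10), 30 higher and 28 lower. Of the 200 tested genes nearest to ccdc103, 100 on each side in the gene order of GRCz12tu, 5 were called without the block (odds ratio 49.2, Fisher's exact p = 3.04e-07) and 19 with it (odds ratio 4.49, interval 2.62 to 7.30, Fisher's exact p = 2.91e-07). The 4 genes that fell without the block lie among them. This window was set after the data were seen and gave the largest odds ratios of the 3 computed. With 50 genes on each side, 2 of 100 were called without the block (interval of the odds ratio 3.27 to 136, Fisher's exact p = 0.00264) and 7 with it (odds ratio 3.15, interval 1.23 to 6.80, Fisher's exact p = 0.00946). With 200 on each side the odds ratios were 24.0 (interval 6.42 to 77.8, Fisher's exact p = 9.15e-06) and 3.66 (interval 2.42 to 5.36, Fisher's exact p = 7.39e-09), so calls were not densest nearest to ccdc103, within wide intervals. zgc:113090, the 11th tested gene from ccdc103, was at 0.31 to 1.17 log2 CPM in controls, and in the mutants of clutches 1, 2 and 4 it was at the lowest value of the library, -5.02 or -4.96. zgc:154169 was at 0.53 to 1.15 log2 CPM in controls and -4.96 to -2.75 in mutants, with the mutant of clutch 4 at the lowest value. LOC100534815 was at 1.09 to 1.21 log2 CPM in controls and -2.08 to -1.17 in mutants, also among the lowest values of the libraries. No fold is given for these 3 genes, since its size depends on values near the lowest in the table. hsd3b7 was 1.69-fold lower, and zgc:198419 was 2.14-fold higher. These clone-named genes were singled out after their values were seen. foxj1a is also on chromosome 3, but 380 tested genes away. Beyond the 200 nearest genes on each side, the blocked odds ratio was 1.98 (interval 1.28 to 2.95, Fisher's exact p = 0.00163).

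**Figure D3:**
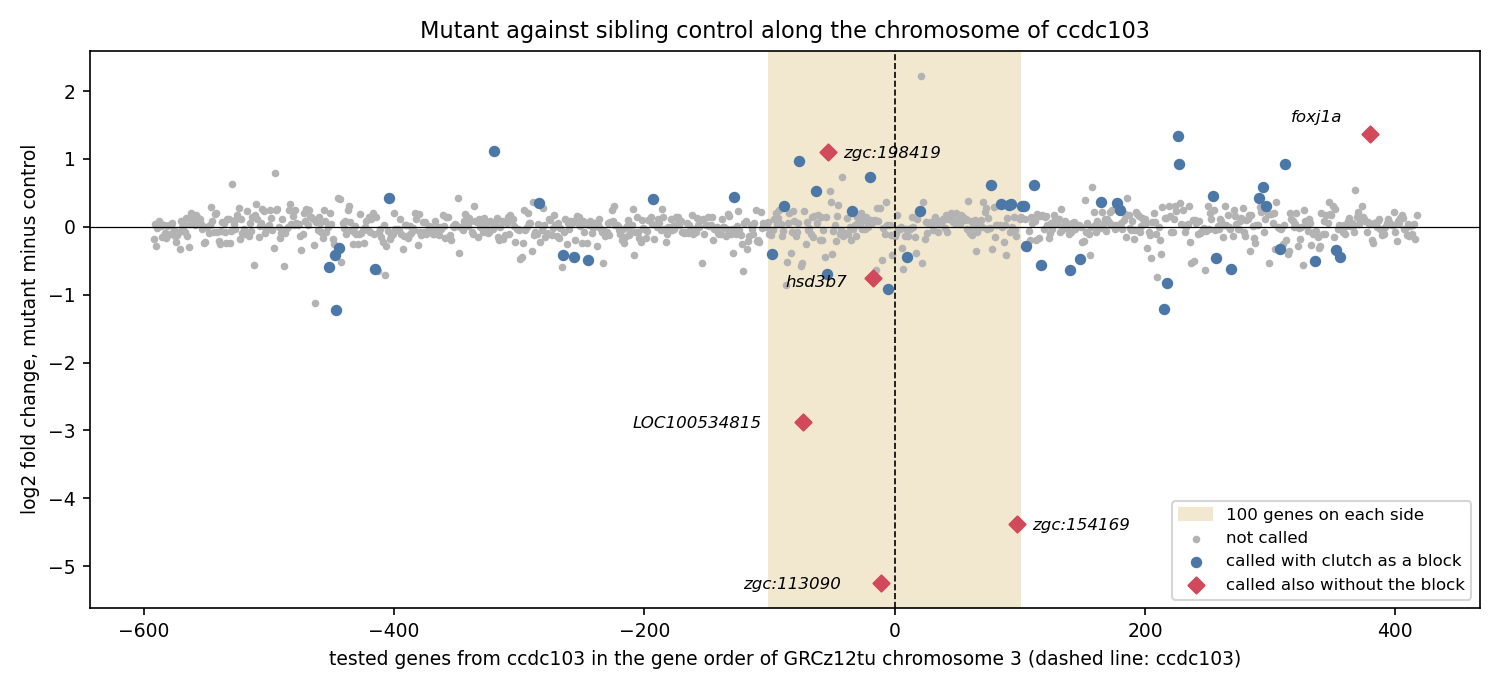
Log2 fold change, mutant minus sibling control (y axis), of the 1010 tested genes of chromosome 3 in the gene order of GRCz12tu, as the number of tested genes from ccdc103 (x axis). Grey points were not called, blue points passed with clutch as a block and red diamonds passed also without it, and the shaded band holds the 100 genes on each side of ccdc103, where 19 genes passed with the block.

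In the authors' deposited table of the same comparison, 24 genes had an adjusted p under 0.05, 20 higher and 4 lower in mutants, and 653 had an unadjusted p under 0.05. Of the 24, 12 were called here without the block and 24 with it. The authors' deposited table has its smallest adjusted p for zgc:154169 (4.96e-06) and for foxj1a and slc5a9 (7.73e-06 each). It also calls motile cilia genes, among them rsph10b (log2 fold change 1.14, adjusted p = 0.00421), dnai2b (1.06, 0.0078), odf3b (1.36, 0.00724), spef2 (0.70, 0.0308) and dnah7 (0.76, 0.0376). Log2 fold changes in the authors' deposited table differed by at most 0.027 from the mean differences computed here.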

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

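The test for a library far from the other 3 of its group was planned, and part of the genes it was run on, those named by rule from the blocked fit, were tests chosen only after the result of that fit was seen. In 15 of 182 groups of 4 libraries (91 genes, both genotypes) the highest or lowest library stood apart by more than Dixon's 95% critical value for its gap over the range of the group, and chance gives about 1 in 20, or 9.1.

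Of the 15, 14 were libraries of clutch 1, with 11 sibling controls and 3 mutants. Among blood cell genes, both libraries of clutch 1 were high. hbbe1.1 was at 9.17 log2 CPM in the control of clutch 1, against 8.53 to 8.58 in the other controls, and at 9.53 in the mutant of clutch 1, against 8.98 to 9.01. hbae3 was at 9.62 in the control, against 8.83 to 8.95, and at 9.74 in the mutant, against 9.23 to 9.30. The connective tissue genes col9a1b and elnb were low in the control of clutch 1, at 6.39 log2 CPM (others 8.02 to 8.36) and 3.32 (others 4.45 to 4.56). Complement genes were high in the same library, c6 at 3.80 (others 3.53 to 3.57) and c7a at 3.64 (others 2.94 to 3.03). So were the muscle genes acta1b at 10.99 (others 10.72 to 10.75) and tnni2a.4 at 10.72 (others 10.29 to 10.35), cxcl12a at 6.92 (others 6.44 to 6.49), and hsd3b7 at 4.65 (others 4.54 to 4.55). dnah5l was low in it, at 2.64 (others 3.09 to 3.16). In the mutant of clutch 1, wt1a was at 3.91 log2 CPM, against 3.38 to 3.42 in the other mutants. The remaining library was the control of clutch 3, where gadd45ab was at 3.86 log2 CPM against 4.41 to 4.45 in the other controls.

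The control of clutch 1 also lay farthest from the rest of its group over all tested genes, with a root mean square difference of 0.448 log2 CPM, followed by the mutant of clutch 1 with 0.371, while the other 6 libraries had 0.252 to 0.320. No explanation of this difference between clutches, technical or biological, was tested. In the fit with clutch as a block, a shift shared by both libraries of a clutch cancels out.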

How the results depend on the processing

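The replicate block was set out before the values were seen, but its use as a result of its own, with its list tests, and the 100 neighbours of ccdc103 were tests chosen only after the data had been seen. Without the block, 15 genes were called, 13 of them at least 2-fold, and 12 of the calls of the authors' table were shared. A replicate block gave 472, 39 and 24, a filter on a mean of 5 CPM 7, 5 and 7, and array weights 41, 22 and 21. Without the genes of the chromosome of ccdc103 there were 8 calls, 7 at least 2-fold. Of the 15 calls, 6 lie on that chromosome and were removed with it, and pdzk1ip1 also lost its call. Leaving out a library or a clutch gave 0 to 25 calls, 0 to 15 at least 2-fold, and 0 to 14 shared with the authors' table. The total was 9 without the control or the mutant of clutch 2, 8 and 7 without the mutants of clutches 3 and 4, 25 without clutch 1, 1 without clutch 2 or clutch 3 and 0 without clutch 4, and fewer libraries give less power. The cause of the other changes was not tested.

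With the block, 472 genes were called, and no replicate block gave 15, 13 at least 2-fold and 12 shared with the authors' table. The filter on a mean of 5 CPM left 10 at least 2-fold and 9 shared with the authors' table. limma without trend and robust gave 50 calls, 18 at least 2-fold. Leaving out a library or a clutch gave 173 to 457 calls, with 235 without clutch 2 and 178 without clutch 4. Median-ratio rescaling gave 14 calls without the block and 432 with it, and it shifted no library by more than 0.051 log2 units.

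Of the 15 lists that passed camera without the block, camera with an estimated correlation called 2 and fry called 2. Of the 18 with the block, these tests called 1 and 3. The direction of the lens list was reversed without the control of clutch 2 (median -0.07) and without clutch 2 (-0.04, and with the block also without either library of clutch 2), and its median ranged from -0.07 to 0.21 without the block and from -0.04 to 0.19 with it. The receptor list went from -0.14 to 0.11 without the block, where it was reversed without the mutant of clutch 1, and with the block it was -0.04 without either library of clutch 1. Neither list had passed camera with all libraries. Over all lists and alternatives, 712 values kept their direction and side of the threshold without the block, 43 became stronger, 22 weaker and 3 reversed, and with the block 740 kept them, 17 became stronger, 20 weaker and 3 reversed. For named genes these were 1527, 8, 56 and none without the block, and 1571 kept and 487 weaker with it, 81 of the latter without the block and 72 without trend and robust. With the block, a library whose clutch mate is left out no longer informs on genotype. Leaving out the clutch, its control or its mutant was thus nearly the same alternative (235, 232 and 231 calls for clutch 2). The totals with the block count each such exclusion 3 times, and their 3 reversals are all the lens list without libraries of clutch 2.

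The odds ratio for calls on the chromosome of ccdc103 stayed above 1 and past the threshold in every alternative that gave a value, at 7.33 to 30.5 over the whole chromosome without the block. For calls on the chromosome of ccdc103 with clutch as a block it was 2.01 to 9.54. Without clutches 2, 3 and 4 the unblocked fit gave 0 or 1 call and so no odds ratio. The difference of ccdc103 ranged from -0.37 to 0.06 and did not pass in any alternative that tested it. Pseudocounts were not run because the values were already logged, count models because the values are not counts, and the 5 Mb window because positions of the files' build were not used here. Depth is unknown, so what it limits cannot be given.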

Other observations

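Tests chosen only after the result was seen were the odds ratio of the 100 neighbours of ccdc103, set once the excess of calls on its chromosome was known, the share of motile cilia genes among calls on the chromosome of ccdc103, the test of the motile cilia list without that chromosome, the sorting of divisions by genotype, the divisions for single lists, and the grouping of genes by the stem of their symbols. The other tests of this section, those in the blocked fit included, were written down before their own values were computed but after the strongest genes had been seen. The gene lists were fixed earlier, before the data were examined. Among 1252 tests of symbol stems (Fisher's exact test on blocked calls, 16049 genes), the dnah genes of dynein heavy chains (5 of 9 higher, adjusted p = 1.06e-05), the rsph genes of radial spokes (4 of 5 higher, adjusted p = 2.34e-05) and the cfap genes (5 of 21 higher, adjusted p = 0.000389) passed, and many of these are members of the motile cilia list. Of the 62 cyp genes, 9 were called lower (adjusted p = 4.4e-05), with a median of -0.10 over the stem, and 4 of the 9 lie on the chromosome of ccdc103. Outside the lists of the report these included cyp3c3, cyp2x9, cyp2k19 and cyp27c1, at log2 fold changes of -0.63, -0.37, -0.42 and -0.40. Beside cyp2k19 on that chromosome, cyp2k21 and cyp2k16 were also called, at -1.23 and -0.31. cyp2k17 and cyp2k8 in the same cluster were at 0.42 and 0.41 and were not called. Fisher's exact test treats such neighbours as independent genes. The prss (3 of 7 lower, adjusted p = 0.0186) and fabp stems (3 of 8 lower, adjusted p = 0.0246) repeat the exocrine pancreas and intestine lists.

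Calls were more frequent among the neighbours of ccdc103 than elsewhere. The odds ratio of being called was 4.49 for the 100 tested genes on each side in the blocked fit. It was 3.15 for 50 and 3.66 for 200. The window of 100 was set once the excess on the chromosome of ccdc103 was known, so its value partly restates that excess. A haplotype linked to the mutation may account for the excess, as a hypothesis. Members of the motile cilia list made up 3.45% of the 58 calls on this chromosome (2 genes, upper 95% bound 11.9%). Only 5 measured members lie on it, so a small share was fixed in advance and does not test them as the source. Whether the linked calls reflect regulation in the larvae or reads of a strain variant that align less well to the reference cannot be separated with these tables. Reads and genotypes were not used here, and a comparison of variants in the reads of foxj1a, hsd3b7 and hspb9 between genotypes would test it.

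The motile cilia list was higher in mutants. Only 5 of its 103 measured members lie on the chromosome of ccdc103. Without them, the remaining 98 gave a camera p of 5.29e-32 in the blocked fit (0.000941 with an estimated correlation), so linked members alone did not give the result. This cannot test an effect of linkage through foxj1a, which is on that chromosome. Its median of 0.52 lay outside the range of -0.054 to 0.042 that held 95% of 10000 random lists of the same mean expression, which argues against a bias of low values from the normalization. It was above 0 in 4 of 4 clutches, so a single clutch was not the source. A candidate explanation is a transcriptional response of ciliated cells to paralysed cilia, with higher foxj1a, or a larger number of such cells, for example in dilated kidney tubules. In situ hybridization of foxj1a and dnah5l with a count of ciliated cells would tell these apart.

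The exocrine pancreas and intestine lists had medians below 0 in mutants, with no member called without the block. Neither list passed camera with an estimated correlation (adjusted p = 0.367 for each without the block and 0.223 for each with it). The median of their 65 genes was -0.46, below the -0.028 to 0.041 of random lists of the same abundance, which argues against a bias of abundant genes, and it was below 0 in 4 of 4 clutches, so a single clutch was not the source. A general developmental delay of mutants may contribute and stays open. Cell cycle genes were higher with a camera p of 0.00329 in the blocked fit, but not with an estimated correlation (p = 0.353), and their median was 0.04. Less growth of the gut in larvae with curved bodies is an untested biological explanation. Staging of larvae by swim bladder and yolk before sampling would test delay.

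The 35 divisions of the 8 libraries into equal groups were compared with the real one. Only 8 of them, the real one included, part all clutch mates, and the others also carry differences between clutches. For genes called without the block chance could not be excluded, with 3 of 35 divisions giving as many (real 15, highest other 146), and the same held at 2-fold (3 of 35, real 13, highest other 51). In each count the other divisions with as many calls keep all clutch mates together. For lists, 7 of 35 gave as many (real 15, highest other 20), so chance could not be excluded. Of the 6 others, 4 keep 3 of 4 libraries with their genotype, the one with 20 lists among them, and so hold part of its difference. The remaining 2 have 2 libraries of each genotype on each side, with at most 17 lists, and 1 of these keeps clutch mates together. For the motile cilia list alone, no other division gave as small a camera p (1.72e-52, smallest other 1.15e-22) or as large an absolute median (0.52, largest other 0.33). The exocrine pancreas median was matched or exceeded in size in 9 of 35 divisions (largest other 0.84) and the intestine median in 8 of 35 (largest other 0.66), so for these lists chance could not be excluded. The 8 divisions that part clutch mates are too few for a share under 0.05, with largest other absolute medians of 0.37 and 0.23. The division with 146 calls puts clutches 1 and 4 against clutches 2 and 3, with clutch mates together, and the one with 53 calls puts clutches 1 and 3 against 2 and 4, which points to a structure of the samples by clutch. Among the 8 divisions that part all clutch mates, as the real one does, the highest other count without the block was 0. With clutch as a block, 8 divisions are too few for a share under 0.05, with 472 genes and 18 lists in the real division (1 of 8 each) and 0 genes and 17 lists as the highest other. The division with 17 lists keeps 3 of 4 libraries with their genotype, and those with 2 of each genotype on each side had at most 6 lists.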
